A study of Mus musculus with 8 samples.

How the data were processed

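RNA sequencing had been carried out on 8 mouse tumours of the 4T1 cell line, 4 given an immune checkpoint inhibitor (ICI) and 4 given the inhibitor and radiation (RI). Groups and replicate numbers were taken from the sample titles. The deposited values were FPKM, fragments scaled for gene length and for the size of the library, in 1 table with 1 column per tumour. HISAT2 and the assembly GRCm38 (mm10) are named, with no version or settings, per the submitters' processing notes. The counting program, the annotation release and any filter on genes are not given in the sources used here.

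The table held 32098 gene rows with Ensembl identifiers and symbols, of which 84 had no symbol. Of these rows 31407 were matched by identifier to GENCODE M21 on GRCm38, which gave the coordinates, the union exon length and the transcript GC content. For each tumour the value of 1 fragment was found from the steps between low FPKM values multiplied by exon length, using values of up to 50 fragments. Between 98.6% and 98.8% of these low values then lay within 0.05 of a whole number, and the recovered totals ran from 27013100 to 42622700 fragments. Fragments were used to give depth, for the share of the mitochondrial genome, for the counts of Sfrp2 and of NK cell receptor genes, and for 1 alternative fit. They were not used for the main test. No pair of libraries agreed within sampling noise (chi-square per gene of at least 32.8), so all 8 were counted separately.

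Genes with at least 1 FPKM in at least 4 of the 8 tumours were tested, 13439 in all. The difference RI minus ICI was tested on log2(FPKM + 1), a pseudocount of 1, with limma (lmFit, then eBayes with trend and robust variance), two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. Each adjusted p given for a gene is from limma with Benjamini-Hochberg adjustment over these genes, unless another fit is named. A difference on this scale understates the change of genes with low FPKM. Means and SDs are of FPKM over the 4 tumours of a group. R 4.3.3 and limma 3.58.1 were used.

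The test was checked on 10 simulated data sets of the same 13439 genes with the means and spreads of these tumours, 200 genes of each set being shifted. Of genes shifted by 1 on the log2 scale 56% were called, of genes shifted by 2 it was 90.3%, and 5.17% of all calls were false. The simulated genes varied independently of one another with a normal spread, whereas genes of real tumours vary together. The share of false calls in the real data was not measured by this check.

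The groups, the tests, 57 gene lists, the genes to be named and the other settings to be tried were fixed before the data were examined. Of 807 list members 795 were found in the table, by symbol or older symbol, and 51 lists had at least 4 members among the genes tested. Lists were tested with limma's camera with a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 51 lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance without comparing them with other genes, were run beside it. Within a list, adjusted p-values over its members alone were also computed. The mean log2(FPKM + 1) of each list per tumour was compared by an exact permutation test over 70 regroupings, two-sided, and so were Sfrp2 and the genes below the filter that are named. With 4 against 4 tumours the smallest two-sided p is 0.0286.

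The genes named are, first, the 12 with the largest rise and the 12 with the largest fall on the log2 scale among called genes whose 4 RI values all lie above or all below the 4 ICI values, leaving out models with no symbol and Gm and Rik models. Second, up to 4 members of each list with the smallest unadjusted p could be named, and for a called list the member with the highest mean FPKM. In addition, Sfrp2, Cd274, Pdcd1, Ctla4, Cd8a, Foxp3, Pecam1, Acta2, Col1a1, Epcam, Cdkn1a and Mki67 are named whatever their values. Gm55118, Rn18s-rs5 and Gm55094 were named after their values were seen.

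These settings were no filter, a mean FPKM of at least 5, pseudocounts of 0.1 and 5, TPM, quantile normalization, upper-quartile scaling, median centring, array weights, eBayes without trend and robust variance, the replicate number as a block, and each library left out in turn. Added after the data were seen were a fit without ICI 1 and RI 4, removal of each library's trend on exon length and then on GC content (lowess, span 0.3), FPKM rescaled to the total without mitochondrially encoded genes and genes outside GENCODE M21, limma voom on the recovered fragments, and the block together with the length and GC correction. The labels give no sequencing or library batch.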

Results

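RNA from 8 mouse tumours grown from 4T1, a mammary carcinoma cell line, was measured by RNA sequencing of the whole tumour. In 4 tumours the treatment was an immune checkpoint inhibitor alone (ICI, replicates 1, 2, 3 and 4), and in 4 it was the inhibitor together with radiation (RI, replicates 1, 2, 4 and 5). The series' design text speaks of 3 replicates per group, whereas 4 per group were listed, and all 8 were used. The labels name neither the inhibitor nor the radiation dose, and they do not say whether an RI tumour lay inside or outside the irradiated field. They also do not say that each tumour came from a separate animal, so p-values measure the spread between these samples, which may be technical in part. The deposited values were FPKM for 32098 genes, on an assembly named as GRCm38.

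Recovered from the steps between low FPKM values, the total was about 32942200, 40329200, 36703500 and 42551300 fragments in ICI 1, 2, 3 and 4, and 27013100, 32163900, 36378100 and 42622700 in RI 1, 2, 4 and 5. In each library 98.6% to 98.8% of the low values lay within 0.05 of a whole number of fragments. All genes of the table on the mitochondrial genome together took 6.73%, 5.28%, 4.37% and 8.14% of the fragments in the ICI tumours and 2.89%, 3.22%, 2.56% and 2.70% in the RI tumours. Libraries ICI 1 and RI 4 stood apart from their groups. In ICI 1, 14750 genes reached 1 FPKM, against 13328 to 13454 in the other ICI tumours, and its mean neutrophil marker level was 8.87 on the log2 scale against 3.14 to 4.52. In RI 4, Gm55118, Rn18s-rs5 and Gm55094 had 342911, 81504 and 11035 FPKM and together took 60.7% of the summed FPKM, against 1.02% to 1.54% in the other RI tumours. Rn18s-rs5 is annotated as related to 18S ribosomal RNA. The first principal component of the genes tested held 50.9% of the variance and placed ICI 1 at −82.1, the other ICI tumours between −30.6 and −0.983, and the RI tumours between 25.6 and 40.0.

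**Figure D1:**
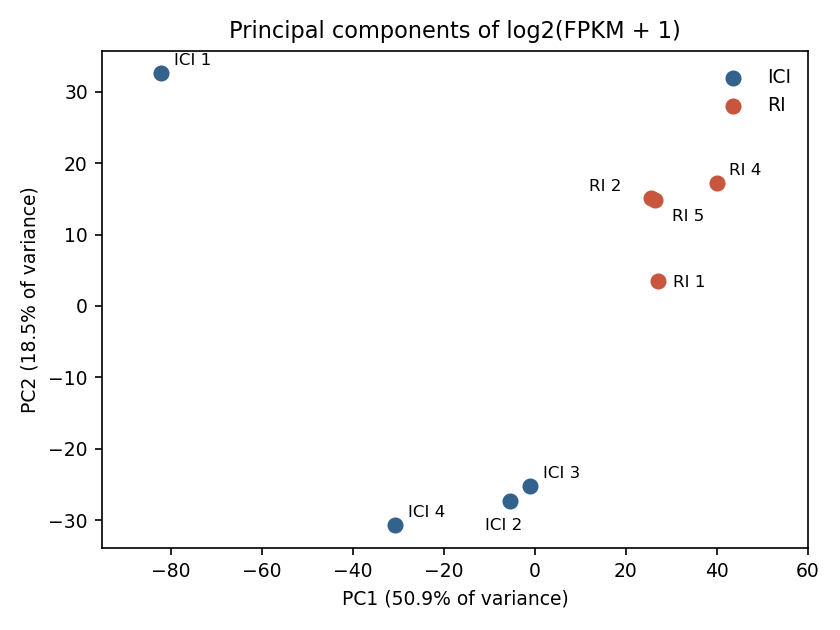
Principal components of log2(FPKM + 1) over the 13439 genes tested, with the first component (50.9% of variance) on the horizontal axis and the second (18.5%) on the vertical axis. Each point is 1 tumour, and ICI 1 lies at −82.1 on the first component while the 4 RI tumours lie between 25.6 and 40.0.

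The design compares tumours given radiation with the inhibitor and tumours given the inhibitor alone, in a study whose title concerns SFRP2-positive fibroblasts and the abscopal effect, the response of a tumour outside the irradiated field. Among the genes that passed, those higher in RI included interferon-stimulated genes, granzymes and perforin, the chemokines Ccl7 and Ccl8, collagens and DNA repair genes. Those lower in RI included genes of the mitochondrial genome, calprotectin (S100a8 and S100a9), immunoglobulin chains and haemoglobin. Of 13439 genes with at least 1 FPKM in at least 4 tumours, 2373 changed by limma with Benjamini-Hochberg adjustment, of which 1486 rose and 887 fell (62.6% up). At least 2-fold changes on the log2(FPKM + 1) scale, which understates the change of low genes, were seen for 293 genes that rose and 233 that fell. In 2281 of the 2373 genes the 4 RI values all lay on one side of the 4 ICI values, as they did for 27.9% of all genes tested, where chance gives 2.86%. With 4 against 4 tumours a call mostly requires such separation, so the 2281 add no support to the calls. The genes tested are not independent of one another, which limits the comparison with chance. The split between rises and falls depended on the scaling, with 48.7% of 2752 calls up after upper-quartile scaling and 48.0% of 3123 after median centring. With TPM the median difference of all genes was 0.11 on the log2 scale, against 0.0115 with FPKM, and 280 genes were called. Without the filter 241 of 32098 genes were called, and with array weights 4319 of 13439. Of the 99 named genes that passed, 42 passed with TPM and 18 without the filter. The count was 336 without ICI 4, 999 without RI 1, 672 without RI 2 and 1017 without RI 5, and 3103 without both ICI 1 and RI 4.

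The size of the difference followed the length of the gene. In the shortest of 10 equal groups of genes (45 to 788 bases of exon) 27 rose and 201 fell, with a median log2 difference of −0.38, and in the longest group (9175 to 41324 bases) 332 rose and 17 fell, with a median of 0.27. Across 13320 genes, which are not independent replicates, Spearman's rho between the log2 difference and exon length was 0.363. Relative to the mean of the 8 tumours the trend was negative in each ICI tumour (rho −0.352 to −0.0950) and positive in each RI tumour (0.179 to 0.407). After the length and GC trends were removed from each library, 2713 genes changed, 1687 of them among the 2373 above and in the same direction. Of the 99 named genes that passed, 83 also passed then. The 16 others were Gbp4, Trac, Ccl3, S100a8, Igkc, Hba-a1, Hbb-bt, Nfatc3, Myh4, Zmat3, Mir7041, Ypel3, F13a1, Cd14, Ankrd37 and Cldn3, with adjusted p from 0.0504 for Myh4 to 0.245 for Ccl3. The log2 difference of S100a8 went from −4.94 to −4.66, of Igkc from −3.75 to −3.42, of Hba-a1 from −3.71 to −3.31 and of Hbb-bt from −3.07 to −2.77, so these lost calls do not show the trends as the source. The difference of Ypel3 went from −1.72 to −1.45, so its lost call does not show this either. It went from −1.80 to −1.24 for Mir7041, from 0.59 to 0.25 for Nfatc3, from 0.67 to 0.34 for Zmat3 and from −0.84 to −0.44 for Cldn3.

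**Figure D2:**
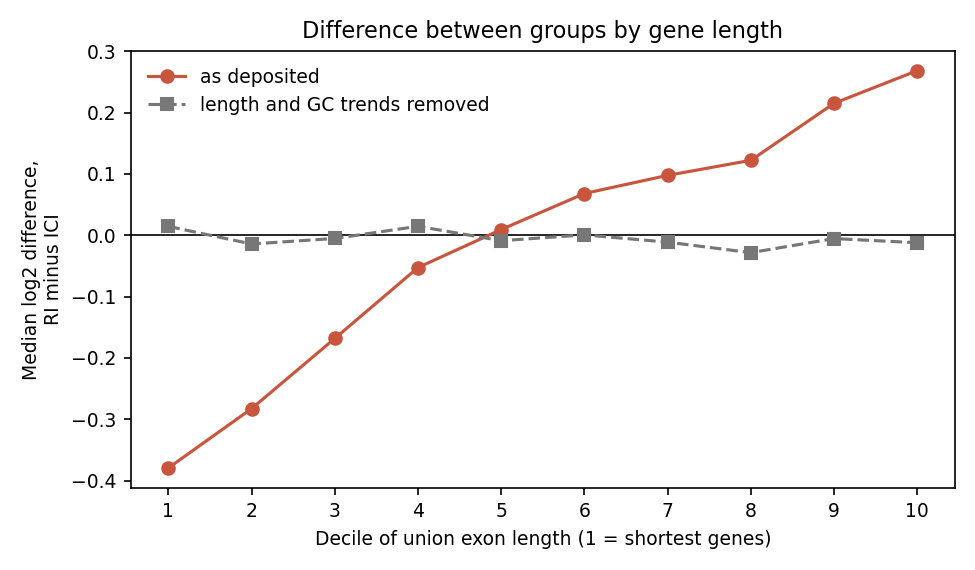
Median log2 difference, RI minus ICI, over 10 groups of 1332 genes ordered by exon length in bases, before and after removal of the length and GC trends. Before removal the medians run from −0.38 in the shortest genes to 0.27 in the longest.

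Sfrp2 encodes a secreted modulator of WNT signalling and marks the fibroblasts named in the study's title. On chromosome 3 (83766321 to 83774316, GRCm38, ENSMUSG00000027996) it averaged 1.89 ± 1.79 FPKM in RI (SD, n = 4) and 0.164 ± 0.191 FPKM in ICI (SD, n = 4), a ratio of 11.5. The 4 ICI tumours had 4, 1, 12 and 40 fragments of Sfrp2, and the RI tumours had 27, 285, 33 and 233, so that RI 2 and RI 5 held most of the signal. The difference of the mean log2(FPKM + 1) was 1.10, with p = 0.0571 in a two-sided exact permutation test over 70 regroupings, whose smallest possible p is 0.0286. The groups overlapped only in that RI 4 (0.421 FPKM) lay below ICI 4 (0.437 FPKM). Without RI 4 it was 1.37, without RI 2 it was 0.75, and with pseudocounts of 5 and 0.1 it was 0.38 and 2.61. With 1 FPKM reached in fewer than 4 tumours, Sfrp2 was not among the genes tested together, and limma over all genes without that filter gave an adjusted p of 0.219.

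Camera with a preset correlation of 0.01 called 16 of the 51 gene lists with at least 4 measured members, 11 of them higher in RI and 5 lower. With an estimated correlation it called 0, and the 1 list at an unadjusted p under 0.05 was the SFRP2 fibroblast neighbours (0.0373). Fry called 5, namely the SFRP2 fibroblast neighbours, type I interferon response, mitochondrially encoded genes, fatty acid metabolism and DNA repair. Their adjusted p by fry ran from 0.0400 to 0.0484. Other divisions of the same 8 tumours into 4 and 4 gave up to 24 lists. In the exact permutation test of each list's mean per tumour 15 lists had an unadjusted p under 0.05. That 0 passed adjustment is nearly fixed by the smallest possible p of 0.0286 over 51 lists.

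**Figure D3:**
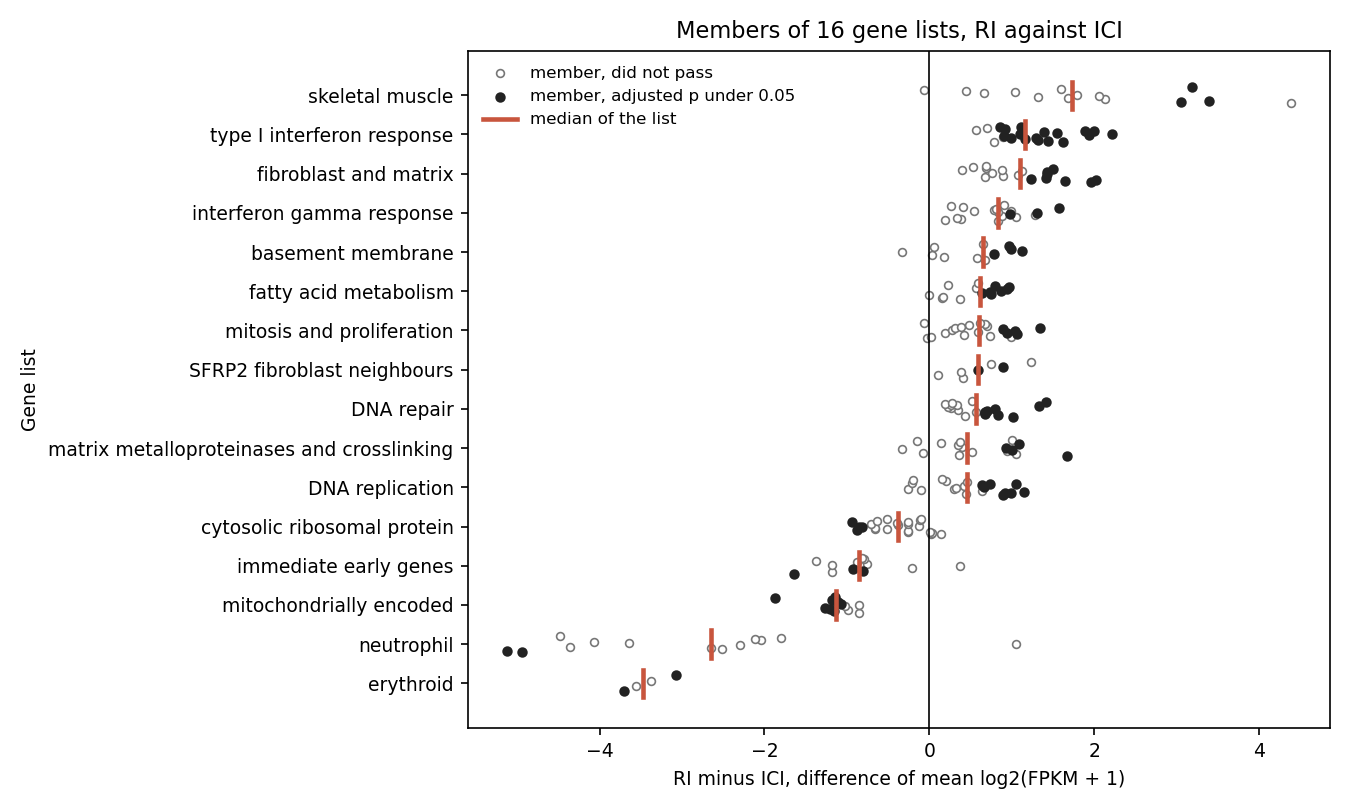
Log2 difference, RI minus ICI, of each measured member of the 16 lists called by camera. Filled points are members that passed limma at an adjusted p of 0.05, open points are members that did not, and the bar marks the median of the list, from −3.47 for erythroid to 1.73 for skeletal muscle. The median of the cytosolic ribosomal protein list, −0.38 here, is 0.10 after quantile normalization.

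Interferon-stimulated genes were higher in the RI tumours. Of 21 measured genes of the type I interferon response, 17 rose and 0 fell, and 19 rose when adjusted over the list alone. The median difference was 1.16 on the log2 scale. Rsad2, the antiviral protein viperin, rose from 2.78 ± 1.31 to 17.2 ± 8.67 FPKM (SD, n = 4 each), a log2 difference of 2.22 with a standard error of 0.34 (adjusted p = 0.0127). Ifit2, which binds foreign RNA, rose from 3.87 ± 0.819 to 12.3 ± 2.68 FPKM (adjusted p = 0.0115). Cmpk2, a mitochondrial nucleotide kinase, rose from 5.10 to 22.4 FPKM (adjusted p = 0.0115), and Ifi44 from 5.19 to 21.6 (adjusted p = 0.0129). Usp18, a brake on interferon receptor signalling, rose from 3.46 to 12.4 FPKM (adjusted p = 0.0117). All 18 measured genes of the interferon gamma response were higher in RI, with a median log2 difference of 0.83. Of these, 10 had an unadjusted limma p under 0.05. After adjustment 3 rose, 0 fell and 15 did not pass, with 4 rising when adjusted over the list alone. The 3 were Irgm2 (17.04 to 53.3 FPKM, adjusted p = 0.0226), Gbp3 (28.7 to 56.3, adjusted p = 0.0339) and Gbp4 (20.6 to 56.4, adjusted p = 0.0496), GTPases of cell-autonomous defence. Camera gave adjusted p = 5.59e-10 for the type I list and 0.00158 for the interferon gamma list, and for both adjusted p = 0.797 with an estimated correlation.

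Among 10 measured genes of cGAS-STING and innate sensing, 4 rose, 1 fell and 5 did not pass, and the counts were the same when adjusted over the list alone. Tlr9, the endosomal receptor for unmethylated DNA, rose from 0.0787 ± 0.0713 to 2.11 ± 0.709 FPKM (adjusted p = 0.0115). Tlr3 rose from 4.34 to 8.30 FPKM (adjusted p = 0.0162), Tlr4 from 3.45 to 6.23 (adjusted p = 0.0174) and Cgas, the cytosolic DNA sensor, from 3.93 to 6.42 (adjusted p = 0.0356). Irf3, the transcription factor downstream of STING, fell from 20.9 to 11.5 FPKM (adjusted p = 0.0309). Camera did not call this list. Of the 13 genes named in this and the preceding paragraph, 12 passed without ICI 1, 11 without ICI 2, 12 without ICI 3, 7 without ICI 4, 9 without RI 1, 6 without RI 2, 9 without RI 4 and 10 without RI 5, with adjusted p of at most 0.125. The type I interferon response had 7 rises without ICI 4, 9 without RI 1 or without RI 2, and 10 without RI 5.

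**Figure D4:**
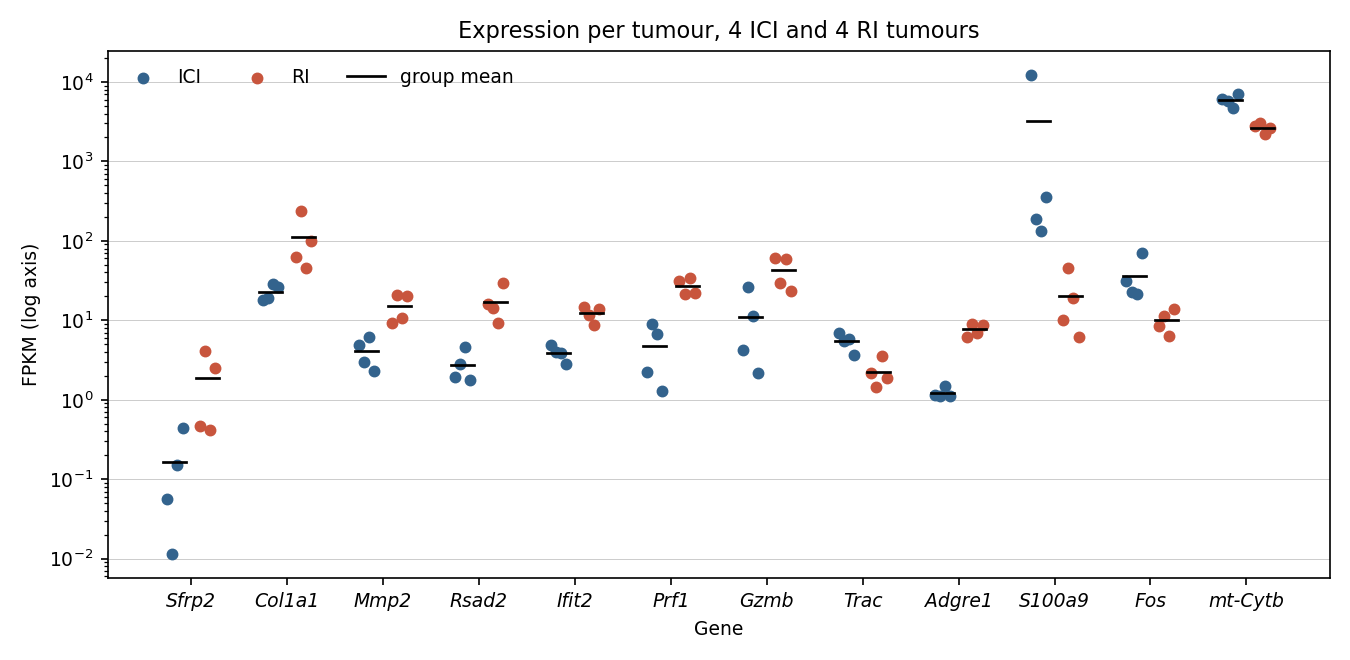
FPKM of selected genes in each tumour on a log axis, with ICI and RI side by side. Each point is 1 tumour and each bar the group mean, such as 4.80 FPKM in ICI and 27.2 FPKM in RI for Prf1.

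Genes of the cytotoxic granule were among the largest rises. Prf1, which forms the perforin pore (chromosome 10, 61297833 to 61304680), rose from 4.80 ± 3.67 to 27.2 ± 6.37 FPKM (SD, n = 4 each), a log2 difference of 2.51 with a standard error of 0.45 (adjusted p = 0.0153). Gzmd (chromosome 14, 56129556 to 56132608) rose from 21.9 ± 31.1 to 135 ± 25.4 FPKM (adjusted p = 0.0335), and Gzmg from 23.1 ± 34.9 to 140 ± 26.5 FPKM (adjusted p = 0.0328). Gzme rose from 8.49 to 50.03 FPKM (adjusted p = 0.0344) and Gzmc from 14.2 to 80.3 FPKM (adjusted p = 0.0315). These 4 granzymes are closely related neighbours whose fragments the counting could have shared, so the value of each one is uncertain. ICI 2 held most of their ICI signal, with 67.5 FPKM of Gzmd against 1.39 to 16.03 in the other ICI tumours and 74.9 of Gzmg against 1.81 to 13.6. Without ICI 2 the log2 difference went from 3.74 to 4.66 for Gzmd and from 3.796 to 4.771 for Gzmg. Gzma rose from 1.25 to 8.38 FPKM (adjusted p = 0.0234) and Gzmb from 10.97 ± 10.9 to 43.5 ± 19.7 FPKM (adjusted p = 0.0481). With Prf1 they were the 3 of 9 measured members of the cytotoxic lymphocyte list that rose, 0 fell, and the count was also 3 when adjusted over the list alone. Camera did not call the list (adjusted p = 0.318), whose median log2 difference was 0.38, with 5 members higher and 4 lower in RI.

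T cell markers did not move in that direction. Of 6 measured T cell genes 0 rose and 1 fell, also when adjusted over the list alone, and that one, Trac, the constant region of the T cell receptor alpha chain, went from 5.49 ± 1.37 to 2.26 ± 0.897 FPKM (adjusted p = 0.0211). Cd8a was 2.84 ± 0.807 FPKM in ICI and 2.29 ± 1.08 in RI (adjusted p = 0.492). Of 3 measured NK cell genes 2 rose, Gzmc and the interleukin 2 receptor subunit Il2rb (3.70 to 8.09 FPKM, adjusted p = 0.0228), and 0 fell, also when adjusted over the list alone. Il2ra rose from 0.307 to 2.05 FPKM (adjusted p = 0.0153), the 1 of 6 regulatory T cell genes to pass, also when adjusted over the list alone, whereas Foxp3 was 0.173 ± 0.0423 FPKM in ICI and 0.101 ± 0.0667 in RI (two-sided exact permutation p = 0.143). Of 9 checkpoint and exhaustion genes 0 passed in limma, also when adjusted over the list alone, 0 had an unadjusted p under 0.05, and limma voom on the recovered fragments called 0, whereas 2 rose without ICI 1, without both ICI 1 and RI 4, or with array weights. Cd274, which encodes PD-L1, was 9.62 ± 2.74 FPKM in ICI and 15.9 ± 7.86 in RI (adjusted p = 0.183), Pdcd1 2.09 ± 0.812 and 2.26 ± 1.10 (adjusted p = 0.923), and Ctla4 1.23 and 1.25 (adjusted p = 0.978). Of the 10 cytotoxic and lymphocyte genes named here that passed, 5 passed without ICI 1, 10 without ICI 2, 9 without ICI 3, 2 without ICI 4, 3 without RI 1, 2 without RI 2, and 4 without RI 4 or without RI 5, with adjusted p of at most 0.115. Prf1 passed in each of these 8 fits, with adjusted p of 0.0483 without ICI 4.

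The chemokines Ccl8 and Ccl7, which attract monocytes, rose, and Ccl3 fell. Ccl8 went from 22.1 ± 15.3 to 127 ± 58.8 FPKM (adjusted p = 0.0200) and Ccl7 from 7.74 ± 5.50 to 35.8 ± 12.4 FPKM (adjusted p = 0.0234), with all 4 RI values of both above all 4 ICI values. Ccl3 fell from 6.90 to 3.88 FPKM (adjusted p = 0.0483). They were the 2 rises and 1 fall among 16 measured inflammatory cytokines and chemokines, with 2 rises and 2 falls when adjusted over the list alone, and camera did not call the list (adjusted p = 0.968). Cd300ld3, a myeloid surface receptor of the CD300 family, rose from 0.947 ± 0.707 to 8.93 ± 3.24 FPKM (adjusted p = 0.0115). Of these 4 genes Cd300ld3 passed with each library left out in turn. Ccl8 and Ccl7 did not pass without ICI 4, RI 1 or RI 2, nor Ccl7 without RI 5, and Ccl3 passed in none of the 8 fits that left out 1 library, with adjusted p of at most 0.103.

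Some markers of neutrophils and red blood cells and some immunoglobulin chains were lower in RI. S100a9, a subunit of the neutrophil protein calprotectin (chromosome 3, 90692632 to 90695721), fell from 3246 ± 6044 to 20.3 ± 17.8 FPKM (SD, n = 4 each; log2 difference −5.12, adjusted p = 0.0380), and S100a8 fell from 1716 to 8.74 FPKM (log2 difference −4.94, adjusted p = 0.0456), with 6549 FPKM in ICI 1. S100a9 was 12310 FPKM in ICI 1 and 187, 134 and 352 FPKM in ICI 2, 3 and 4, while the RI tumours lay between 6.20 and 45.7 FPKM. Of 13 measured neutrophil genes 0 rose and 2 fell, and adjusted over the list alone 1 rose and 9 fell. Without ICI 1 there were 10 falls and 1 rise, without ICI 3 there were 4 falls, and without ICI 1 the log2 difference was −3.65 for S100a9 (adjusted p = 0.0140) and −3.39 for S100a8 (adjusted p = 0.0129). Without ICI 2, ICI 4 or any 1 RI tumour there were 0 falls, and limma voom on the recovered fragments called 0 of the 13, with an adjusted p of 0.0865 for S100a9, and 0 of the erythroid genes. The immunoglobulin chains Igkc (399 ± 672 to 11.7 ± 9.42 FPKM, adjusted p = 0.0477), Igha (15.9 ± 5.43 to 1.88 ± 1.25, adjusted p = 0.0115) and Iglc1 (3.45 to 0.282, adjusted p = 0.0115) fell. Of 5 measured plasma cell genes 1 rose and 2 fell, with 1 and 3 when adjusted over the list alone, and camera did not call the list (adjusted p = 0.124). Hba-a1 (194 ± 143 to 18.5 ± 12.4 FPKM, adjusted p = 0.0428) and Hbb-bt (65.6 to 9.90, adjusted p = 0.0476) were the 2 of 4 measured erythroid genes that fell, and all 4 fell when adjusted over the list alone. The globin genes have near-identical copies, so the value of each is uncertain. Camera gave adjusted p = 0.00105 for neutrophil and 0.0101 for erythroid, and for both adjusted p = 0.797 with an estimated correlation. Of these 7 genes 5 passed without ICI 1 or without ICI 3, 4 without RI 5, and 2 (Igha and Iglc1) without ICI 2, ICI 4, RI 1, RI 2 or RI 4, with adjusted p of at most 0.116.

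Some collagens and other matrix genes of fibroblasts were higher in RI. Of 18 measured genes of the fibroblast and matrix list, 8 rose and 0 fell, 13 rose when adjusted over the list alone, and the median log2 difference was 1.10. Col1a1, the main chain of type I collagen (chromosome 11, 94936224 to 94953042), rose from 22.9 ± 5.17 to 111 ± 88.1 FPKM (SD, n = 4 each), a log2 difference of 1.96 with a standard error of 0.46 (adjusted p = 0.0254). Its value was 239 FPKM in RI 2 and 62.0, 45.3 and 99.3 in RI 1, 4 and 5. Fbn1, the microfibril protein fibrillin, rose from 0.966 to 4.78 FPKM (adjusted p = 0.0134) and Col5a2 from 3.76 to 12.9 FPKM (adjusted p = 0.0207). Of 16 metalloproteinase and crosslinking genes 4 rose (5 adjusted over the list alone) and 0 fell. They were Mmp2, a gelatinase (4.07 ± 1.73 to 15.3 ± 6.15 FPKM, adjusted p = 0.0159), Mmp14, which activates it (23.7 to 47.6, adjusted p = 0.0178), their inhibitor Timp2 (73.6 to 137, adjusted p = 0.0296) and Loxl2 (1.73 to 5.24, adjusted p = 0.0396). Of 11 basement membrane genes 4 rose (7 adjusted over the list alone) and 0 fell, among them Hspg2, which encodes perlecan (34.0 to 66.9 FPKM, adjusted p = 0.0129), and the laminin chain Lamc1 (37.2 to 77.8, adjusted p = 0.0234).

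Of 7 measured genes of the list of SFRP2 fibroblast neighbours, 2 rose (3 adjusted over the list alone) and 0 fell. They were Nfatc3, a transcription factor (3.90 to 6.33 FPKM, adjusted p = 0.0233), and Ccn4, a target of WNT signalling (0.8289 to 2.41 FPKM, adjusted p = 0.0305). Camera gave adjusted p = 7.08e-06 for fibroblast and matrix, 0.0248 for basement membrane, 0.0328 for the SFRP2 fibroblast neighbours and 0.0413 for metalloproteinases and crosslinking, and for each of them adjusted p = 0.797 with an estimated correlation. After the length and GC trends were removed the adjusted p was 0.138 for basement membrane, whose median went from 0.65 to 0.54, and 0.0849 for the SFRP2 fibroblast neighbours, whose median went from 0.59 to 0.30. Fry in the main fit gave adjusted p = 0.0400 for the SFRP2 fibroblast neighbours. It gave 0.0697 for fibroblast and matrix and for basement membrane, and 0.103 for metalloproteinases and crosslinking. Camera did not call the myofibroblastic list, with 1 rise among 11 genes (0 adjusted over the list alone, 3 with array weights), or the pericyte list, with 0 of 9 genes past limma or limma voom, 0 at an unadjusted p under 0.05, and 1 rise with TPM, with array weights or without both ICI 1 and RI 4. Acta2, the smooth muscle actin, was 13.1 ± 7.34 FPKM in ICI and 9.18 ± 6.54 in RI (adjusted p = 0.492). In vascular endothelium 0 of 13 genes passed limma, limma voom or adjustment over the list alone, 1 had an unadjusted p under 0.05, and 1 rose with array weights, without ICI 1 or without both ICI 1 and RI 4. The list median was −0.52, or −0.0610 without ICI 1 and 0.12 with array weights. Pecam1 was 11.1 ± 11.5 FPKM in ICI, with 28.3 in ICI 1, and 8.51 ± 4.29 in RI (adjusted p = 0.955). Of the 11 matrix genes named in this and the preceding paragraph that passed, 10 passed without ICI 1, 9 without ICI 2 or without ICI 3, 2 without ICI 4, 6 without RI 1, 5 without RI 2 or without RI 5, and 11 without RI 4, with adjusted p of at most 0.0855. The fibroblast and matrix list had 1 rise without ICI 4 or without RI 5, 4 without ICI 2 or without RI 2, 5 without ICI 3 or without RI 1, and 12 without both ICI 1 and RI 4. Camera did not call the SFRP2 fibroblast neighbours without ICI 3 (adjusted p = 0.0620), RI 2 (0.0516) or RI 4 (0.05004) or with the total without mitochondrial and unmatched genes (0.050003), basement membrane without RI 2 (0.0530), or metalloproteinases and crosslinking without ICI 3 (0.0620) or RI 2 (0.0704). It did not call the last of these with a mean FPKM of at least 5 (0.179), a pseudocount of 5 (0.0517) or the total without mitochondrial and unmatched genes (0.0593) either.

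Some genes of skeletal muscle and mast cells were higher in RI, and adipocyte markers were high in RI 2. Of 14 measured skeletal muscle genes 3 rose, also when adjusted over the list alone, and 0 fell: Atp2a1, the calcium pump of fast muscle (4.26 to 34.1 FPKM, adjusted p = 0.0335), Ckm, the muscle creatine kinase (1.62 to 18.9, adjusted p = 0.0258), and the myosin Myh4 (2.39 to 29.0, adjusted p = 0.0490). Mybpc1, a myosin-binding protein, rose from 1.03 to 8.14 FPKM (adjusted p = 0.0329), and Acta1, skeletal actin, was 42.4 ± 63.2 FPKM in ICI and 233 ± 144 in RI (adjusted p = 0.0819, and 0.0313 without ICI 3). The mean log2 level of the muscle list was 1.11, 2.81, 4.05 and 0.924 in the ICI tumours and 3.90, 4.57, 4.97 and 3.07 in the RI tumours. Camera gave the list adjusted p = 0.00431, and adjusted p = 0.797 with an estimated correlation. It did not call the list without RI 4 (adjusted p = 0.0636), without both ICI 1 and RI 4 (adjusted p = 0.347) or with array weights (adjusted p = 0.135). The median log2 difference of the list was 1.73 in the main fit, and 1.31, 0.85 and 1.01 in these fits, in that order. The adipocyte list had 0 of 5 members past limma, limma voom or adjustment over the list alone and 1 at an unadjusted p under 0.05, 1 rose with TPM, and its mean log2 level was 5.56 in RI 2 against 2.08 to 2.21 in the other RI tumours and 0.881 to 2.27 in the ICI tumours. Cfd, the adipocyte protease adipsin, was 223 FPKM in RI 2. Of 6 measured mast cell genes 3 rose and 0 fell, with 4 and 1 when adjusted over the list alone, namely the proteases Tpsb2 (1.28 to 9.98 FPKM, adjusted p = 0.0254), Cma1 (0.793 to 6.04, adjusted p = 0.0263) and Cpa3 (0.831 to 4.02, adjusted p = 0.0209). Camera did not call the mast cell list. Limma voom on the recovered fragments called 0 muscle and 0 mast cell genes. Of the 7 muscle and mast cell genes that passed, 2 passed without ICI 1, 5 without ICI 2, 7 without ICI 3, 0 without ICI 4, 1 without RI 1 or without RI 2, 3 without RI 4 and 4 without RI 5, with adjusted p of at most 0.126.

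Some genes of DNA repair, DNA replication and mitosis were higher in RI. Of 19 measured DNA repair genes 9 rose (11 adjusted over the list alone) and 0 fell, with a median log2 difference of 0.57. After the length and GC trends were removed that median was 0.39 (camera, adjusted p = 0.00119). Atm, the kinase that signals double-strand breaks, rose from 2.26 ± 0.508 to 7.22 ± 1.38 FPKM (SD, n = 4 each), a log2 difference of 1.33 with an adjusted p of 0.0115. Brca1 rose from 2.84 to 6.59 FPKM (adjusted p = 0.0145), and Rpa1, which coats single-stranded DNA, from 13.2 to 36.5 (adjusted p = 0.0171). Of 20 DNA replication genes 8 rose (9 adjusted over the list alone) and 0 fell, among them the helicase subunits Mcm6 (33.0 to 70.4 FPKM, adjusted p = 0.0232) and Mcm4 (21.9 to 40.9, adjusted p = 0.0219). Of 20 genes of mitosis and proliferation 5 rose (9 adjusted over the list alone) and 0 fell, among them the mitotic kinesin Kif20a (7.44 to 20.6 FPKM, adjusted p = 0.0153) and the cyclin Ccna2 (24.3 to 49.2, adjusted p = 0.0287). The proliferation marker Mki67 was 45.8 ± 9.93 FPKM in ICI and 44.5 ± 6.34 in RI (adjusted p = 0.944). Camera gave adjusted p = 7.08e-06 for DNA repair, 0.00501 for DNA replication and 0.000959 for mitosis and proliferation, and for all 3 adjusted p = 0.797 with an estimated correlation. With array weights it was 0.0552 for DNA replication. Of the 7 genes named here that passed, 7 passed without ICI 1, ICI 2 or ICI 3, 2 without ICI 4, 4 without RI 1, RI 2 or RI 5, and 6 without RI 4, with adjusted p of at most 0.0804. DNA replication had 0 rises without ICI 4, RI 1, RI 2 or RI 5 and 3 without RI 4, mitosis and proliferation 0 to 3 without ICI 4 or any 1 RI tumour, and DNA repair 2 to 4 without ICI 4, RI 1, RI 2 or RI 5.

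Targets of p53 did not move together. Of 18 measured genes of the p53 and DNA damage response 3 rose and 1 fell, also when adjusted over the list alone, and camera did not call the list. Ccng1 (12.4 to 20.5 FPKM, adjusted p = 0.0171) and Zmat3 (1.36 to 2.75, adjusted p = 0.0234) rose, and the pro-apoptotic gene Bax fell from 51.9 ± 3.12 to 28.2 ± 5.89 FPKM (adjusted p = 0.0162). Cdkn1a, the p53-induced inhibitor of the cell cycle, was 15.1 ± 7.47 FPKM in ICI and 19.2 ± 5.29 in RI (adjusted p = 0.404), but its adjusted p was 0.0137 without both ICI 1 and RI 4. Of Ccng1, Zmat3 and Bax 0 passed without ICI 4, 1 without RI 2, and 2 without ICI 2, RI 1 or RI 5, with adjusted p of at most 0.0640.

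Most protein-coding transcripts of the mitochondrial genome fell. Of 13 measured genes 9 fell (10 adjusted over the list alone) and 0 rose, with a median log2 difference of −1.13, or −0.74 after the length and GC trends were removed. After quantile normalization the median was −0.38 with 3 falls, without mt-Cytb, mt-Atp6 and mt-Co3 (adjusted p of at most 0.527), and with TPM there was 1 fall. Mt-Cytb, the cytochrome b of complex III, fell from 5872 ± 963 to 2649 ± 341 FPKM (adjusted p = 0.0136), and mt-Atp8 from 469 ± 156 to 125 ± 34.8 FPKM (adjusted p = 0.0129). Nuclear copies of mitochondrial genes can share fragments with them. Of 20 nuclear genes of oxidative phosphorylation 1 rose and 4 fell, also when adjusted over the list alone. The short genes Uqcrb (71.3 to 33.9 FPKM, adjusted p = 0.0199) and Ndufa1 (50.9 to 25.9, adjusted p = 0.0229) fell, and the longer Sdha rose from 26.3 to 49.3 (adjusted p = 0.0200). Of 23 cytosolic ribosomal protein genes 4 fell (7 adjusted over the list alone) and 0 rose, among them Rps18 (56.4 to 29.0 FPKM, adjusted p = 0.0223) and Rpl11 (378 to 204, adjusted p = 0.0279), with a list median of −0.38 that turned to 0.10 after quantile normalization (camera, adjusted p = 0.893). The pseudogene Rpl15-ps2 fell from 33.4 to 9.83 FPKM (adjusted p = 0.0234), a value that its parent gene could share. Camera gave adjusted p = 8.36e-07 for the mitochondrially encoded list and 0.00172 for cytosolic ribosomal protein, and for both adjusted p = 0.797 with an estimated correlation. Of 12 housekeeping genes 2 rose and 2 fell, with 2 and 3 when adjusted over the list alone. Gapdh went from 63.5 to 35.9 FPKM (adjusted p = 0.0263). It was the 1 fall among 15 glycolysis genes, of which 10 were higher in RI, with a median log2 difference of 0.30. Camera did not call that list (adjusted p = 0.923). Among mt-Cytb, mt-Atp8, mt-Atp6, mt-Co3 and the other 7 genes named here, 11 passed without ICI 1, 9 without ICI 2, 11 without ICI 3, 4 without ICI 4, 10 without RI 1, 8 without RI 2, 9 without RI 4 and 6 without RI 5, with adjusted p of at most 0.0850. The ribosomal protein list had 9 falls without ICI 1 and 0 to 2 without any 1 of the other 7 tumours.

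Some immediate early transcription factors fell and some genes of lipid synthesis rose. Of 12 immediate early genes 3 fell (4 adjusted over the list alone) and 0 rose. They were Fos (36.4 to 10.1 FPKM, log2 difference −1.64, adjusted p = 0.0249), Jun (109.8 to 62.1, adjusted p = 0.0154) and Junb (129.9 to 70.2, adjusted p = 0.0316). Of 14 genes of fatty acid metabolism 7 rose, also when adjusted over the list alone, and 0 fell. Acaca, which makes malonyl-CoA (2.25 to 5.27 FPKM, adjusted p = 0.0115), the fatty acid synthase Fasn (26.5 to 49.4, adjusted p = 0.0130) and the desaturase Scd2 (33.3 to 65.6, adjusted p = 0.0153) were among them. The mean log2 level of the list was 4.61 in RI 2, the tumour with high adipocyte markers, 3.89 to 4.12 in the other RI tumours and 3.37 to 3.76 in the ICI tumours. The median log2 difference of the list was 0.62, or 0.39 after the length and GC trends were removed. Camera gave adjusted p = 0.00172 for immediate early genes and 0.00158 for fatty acid metabolism, and for both adjusted p = 0.797 with an estimated correlation. Of the 3 immediate early genes 1 passed without ICI 4, RI 1 or RI 2, and 2 without ICI 2, ICI 3 or RI 4, with adjusted p of at most 0.0697. Fatty acid metabolism had 2 rises without ICI 4, 3 without RI 2 and 4 without RI 1 or without RI 5. Acaca and Fasn passed with each library left out, and Scd2 did not pass without ICI 4, with an adjusted p of 0.0530.

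The remaining large falls were in 3 genes of no shared list. The microRNA genes Mir1258, at 3.38 ± 2.48 FPKM in ICI and listed at 0 in all 4 RI tumours (adjusted p = 0.0126), and Mir7041 (4.92 to 0.752 FPKM, adjusted p = 0.0254) have annotated lengths of 60 and 52 bases, below the size of a usual library fragment. At such lengths these FPKM values rest on few fragments, so both falls are uncertain. Limma voom on the recovered fragments gave adjusted p = 0.0151 for Mir1258 and 0.0602 for Mir7041. Ypel3 fell from 48.2 ± 47.4 to 10.6 ± 2.84 FPKM (adjusted p = 0.0499), with 119 FPKM in ICI 1. Mir7041 and Ypel3 did not pass without ICI 2, RI 2 or RI 5, and Ypel3 did not pass without ICI 3, ICI 4, RI 1 or RI 4 either, with adjusted p of at most 0.10003. Epcam, an epithelial adhesion molecule, was 2.08 ± 2.46 FPKM in ICI and 0.345 ± 0.486 in RI (two-sided exact permutation p = 0.371).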

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

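The tests in this part were chosen after the results they bear on had been seen, except the correlation with length over genes without the ribosomal and respiratory families. A tumour is listed below where its gap to the nearest of the other 3 tumours of its group took up more of the group's range than Dixon's limit for 4 values allows. Chance alone gives about 1 in 20 groups such a tumour, and 23 of 338 groups examined (6.80%) had one. Of the 23 values, 9 were in ICI 1, 5 in RI 4, 3 in RI 5, 2 in RI 2, 2 in ICI 4, 1 in ICI 3 and 1 in RI 1.

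In ICI 1 the value of Igkc was 1407 FPKM, against 47.9 to 85.0 in the other ICI tumours, while Lamc1 was 19.1 (41.8 to 44.6) and Fscn1 21.6 (52.7 to 61.7). The mean log2 levels of lists in ICI 1 were 3.53 for myofibroblastic genes (3.76 in the others), 2.97 for pericyte (1.94 to 2.09), 3.90 for the p53 and DNA damage response (3.04 to 3.19), 5.21 for oxidative phosphorylation (5.66 to 5.70) and 8.01 for cytosolic ribosomal protein (8.73 to 8.85). The number of genes at 1 FPKM or more was 14750 in ICI 1, against 13328 to 13454. In ICI 4 the mean log2 level of angiogenic factors was 2.93 (2.76 to 2.79 in the others) and that of checkpoint and exhaustion genes 2.17 (2.62 to 2.71). In ICI 3 Adgre1 was 1.47 FPKM (1.12 to 1.15).

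In RI 4 the value of Ccl7 was 17.4 FPKM, against 40.0 to 44.5 in the other RI tumours. The mean log2 level was 3.13 for alternatively activated macrophage genes (3.93 to 4.01) and 2.81 for inflammatory cytokines and chemokines (3.54 to 3.62). Genes outside GENCODE M21 took 17.5% of the total in RI 4 (0.555% to 0.678% in the others), and Gm55118, Rn18s-rs5 and Gm55094 together 60.7% of the summed FPKM (1.02% to 1.54%). In RI 5 Hba-a1 was 0.289 FPKM (21.9 to 27.4), Myh4 was 2.57 FPKM (29.8 to 44.3), and the mean log2 level of erythroid genes was 0.0915 (4.27 to 4.68). In RI 2 Cma1 was 13.1 FPKM (3.25 to 4.03) and the mean log2 level of adipocyte genes 5.56 (2.08 to 2.21). In RI 1 Gbp3 was 77.3 FPKM (47.9 to 50.51).

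Of the 35 ways to divide the 8 tumours into 4 and 4, 1, the real one, gave as many as 2373 changed genes, and the highest of the others gave 2. Each other division mixes the 2 groups, so the difference between the groups adds to the spread and few calls are left. The count thus sets the real division apart. With only 35 divisions it does not exclude chance, and it cannot tell treatment from another difference shared by a group. For the lists called by camera with a preset correlation, 20 of the 35 divisions gave at least the real 16, and the highest of the others gave 24, so chance is not excluded for the count of lists.

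Short genes were lower and long genes higher in RI. With ribosomal protein, mitochondrial, respiratory chain and proteasome genes left out, Spearman's rho between the difference and exon length was still 0.308 over 10907 protein-coding genes, against 0.327 with them, which argues against a joint fall of those families as the source of the trend. A length-dependent bias of measurement, such as a difference in RNA integrity or fragment size between the libraries, may account for the trend, and no integrity value was used here to test it. The sign of the trend followed the treatment in 8 of 8 libraries, so that a bias shared by a group and an effect of radiation cannot be told apart in this design. The trend alone does not account for the changed genes, since 1687 of 2373 remained called in the same direction after each library's length and GC trends were removed.

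Some matrix and muscle genes were higher in RI, and adipocyte markers were high in RI 2. The fibroblast and matrix score was 1.13 higher in RI (SE 0.313). It was 0.756 higher (SE 0.239) with the adipocyte score, whose Cfd reached 223 FPKM in RI 2, as a covariate, and 1.20 higher (SE 0.462) with the muscle score, whose Acta1 averaged 233 FPKM in RI, which argues against fat or muscle next to the tumour as the whole source. The median of the list was 0.96 after the length and GC trends were removed, against 1.10, so the trend is not the whole source either. A larger or more active fibroblast share after radiation stays open as a hypothesis, and so does fat as the source of a part of the difference.

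Granzymes and perforin were higher in RI while T cell markers were not. The T cell score, over the 6 measured of 17 listed genes, differed by −0.353 (SE 0.261). That argues against a larger share of T cells as the source of a log2 difference of 2.51 in Prf1. The median of the T cell list was −0.34, or −0.13 after the length and GC trends were removed. The score does not bear on a larger cytotoxic subset within an unchanged T cell share. The log2 difference of Prf1 was 2.58 after the length and GC trends were removed, so the trend is not its source. The share of fragments in 7 NK cell receptor genes was 1.57 times as high in RI (log2 difference 0.80, SE 0.784, two-sided exact permutation p = 0.371), and at this depth, with 24 to 189 fragments per library, a larger NK cell share cannot be told apart from no change. A higher output of granzymes per cell may also account for the rise, and no test of it was possible on whole tumours.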

How the results depend on the processing

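Array weights, the block and the left-out libraries were planned, whereas the fit without ICI 1 and RI 4, the length and GC corrections, the total without mitochondrial and unmatched genes and limma voom were chosen after the data were seen. The count of changed genes, 2373, was 241 with no filter on low values, where 32098 genes were tested, 280 with TPM and 4319 with array weights. With 1 library left out, or ICI 1 and RI 4 together, it lay between 336 and 3103. The labels do not say whether the numbers pair the tumours. The deviations of tumours with the same number correlated at −0.0923, −0.120 and −0.124, and no tumour correlated best with its own number. These few values show no sign of pairing but cannot exclude it. With the replicate number as a block the count was 22, and 3 together with the length and GC correction, over 6 tumours in both. The other planned and added settings gave counts within 1.5 times of 2373. TPM divides each value by the summed FPKM of its library, which was 717092 in RI 4 and 358243 to 494399 in the other tumours. It thus lowered the values of RI 4 against those of its group. Whether this accounts for the count of 280 was not tested. The cause of the other differences was not tested either, except that the block and the left-out fits use fewer tumours. The 16 called lists were 0 with an estimated correlation (1 at an unadjusted p under 0.05) and 5 with fry, while 13 to 16 of them were called by camera in each other setting. With the length correction alone camera did not call basement membrane (adjusted p = 0.197) or the SFRP2 fibroblast neighbours (0.0660), and with the block and the length and GC correction it did not call these (0.0810 and 0.0726) or cytosolic ribosomal protein (0.0810). The basement membrane median was 0.65 in the main fit, 0.46 with the length correction and 0.59 with the block and correction. For the SFRP2 fibroblast neighbours these medians were 0.59, 0.33 and 0.37. For cytosolic ribosomal protein the median was −0.38 in the main fit and −0.24 with the block and correction. The list scores were not tested with the block, and elsewhere their smallest possible p, 0.0286 or more, nearly fixed the 0 past adjustment.

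The Sfrp2 difference of 1.10 kept its direction in each setting that gave a value, but it was 0.38 with a pseudocount of 5, 1.73 with TPM, 2.61 with a pseudocount of 0.1 and 3.69 with limma voom. Its exact permutation p was 0.0286, the smallest possible, after quantile normalization (1.14), with the total without mitochondrial and unmatched genes (1.14) and without RI 4 (1.37), where fewer tumours remained, and with libraries left out the difference ran from 0.75 to 1.37. In the main values the groups overlapped only where RI 4 (0.421 FPKM) lay below ICI 4 (0.437 FPKM). At the smallest possible p they no longer overlapped. Why the size of the difference varied was not tested. No value of Sfrp2 was given with the stricter filter, array weights, eBayes without trend, or the length and GC corrections, since these fits do not change its test or do not hold it.

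Of the 99 named genes that passed, 0 reversed and 0 passed in every setting, while 38 passed in at least 20. The number that passed was 18 with no filter, 42 with TPM, 11 with the block, 28 without ICI 4, 40 without RI 2, 51 without RI 1, 83 after the length and GC correction and 83 with limma voom. Cdkn1a was called with array weights (0.72) and without ICI 1 and RI 4 (0.87), and Acta1 without ICI 3 (5.67). Genes that had not passed changed sign as follows, without passing, and the cause was not tested. With array weights the difference was −0.41 for Pdcd1, −0.12 for Ctla4, 0.81 for Pecam1 and 0.26 for Acta2. For Ctla4 it was −0.00346 after upper-quartile scaling and −0.0368 after median centring. With TPM it was 0.0502 for Pecam1 and 0.0679 for Mki67, which was at 0.0322 after quantile normalization and 0.14 with the block. With libraries left out the differences ran from −0.17 to 0.27 for Pdcd1, from −0.0568 to 0.10 for Ctla4, from −0.33 to 0.66 for Pecam1, from −0.89 to 0.0819 for Acta2 and from −0.17 to 0.0599 for Mki67.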

Other observations

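Some macrophage markers rose. The gene with the smallest p over all 13439 tested was Adgre1, which encodes the macrophage surface protein F4/80. It rose from 1.22 ± 0.171 to 7.68 ± 1.37 FPKM (SD, n = 4 each), a log2 difference of 1.96 with a standard error of 0.15 (limma, adjusted p = 0.00158), with all 4 RI values above all 4 ICI values. Mrc1, the mannose receptor, rose from 7.68 to 26.5 FPKM (adjusted p = 0.0207). They were the 2 of 13 measured macrophage genes that rose, also when adjusted over the list alone, and camera did not call the list (adjusted p = 0.122, and 0.0300 after the length and GC trends were removed). Folr2, a marker of tissue-resident macrophages, rose from 0.406 to 2.35 FPKM (adjusted p = 0.0257), and of 9 monocyte genes F13a1 rose (3.53 to 10.1, adjusted p = 0.0369) and Cd14 fell (49.1 to 25.6, adjusted p = 0.0498), with 1 and 1 when adjusted over the list alone. H2-Aa, an MHC class II chain, fell from 74.7 to 35.5 FPKM (adjusted p = 0.0446), the 1 of 8 class II genes to pass, with 0 when adjusted over the list alone. With quantile normalization, with array weights or without both ICI 1 and RI 4 the class II list had 1 rise and 0 falls. Of these 6 genes Adgre1 passed with each library left out in turn, 4 passed without ICI 1, ICI 2 or RI 1, 3 without ICI 3, RI 4 or RI 5, and 1 without ICI 4 or RI 2, with adjusted p of at most 0.116.

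Of 8 measured WNT pathway genes 3 rose (4 adjusted over the list alone) and 0 fell, and camera did not call the list (adjusted p = 0.0944). Ctnnb1, which encodes beta-catenin, rose from 72.7 to 127 FPKM (adjusted p = 0.0295), the WNT inhibitor Apcdd1 from 4.52 to 9.43 (adjusted p = 0.0192) and the ligand Wnt7b from 27.0 to 49.7 (adjusted p = 0.0463). Tgfbr2, a receptor for TGF-beta, rose from 14.2 to 30.3 FPKM (adjusted p = 0.0119), the 1 of 12 genes of its list to pass, also when adjusted over the list alone. Complement C3 rose from 34.3 to 102 FPKM (adjusted p = 0.0223), the 1 of 10 inflammatory fibroblast genes to pass. Fscn1 rose from 48.6 to 107 FPKM (adjusted p = 0.0359) and the adhesion molecule Vcam1 from 9.17 to 21.6 (adjusted p = 0.0314). Vegfa (35.3 to 18.2 FPKM, adjusted p = 0.0455) and Ankrd37 (14.6 to 5.56, adjusted p = 0.0309) were the 2 of 18 hypoxia genes that fell, with 0 when adjusted over the list alone. Of 9 epithelial genes 1 rose and 2 fell, also when adjusted over the list alone, the falls being in Esrp2, an epithelial splicing factor (3.94 to 1.48, adjusted p = 0.0337), and the claudin Cldn3 (24.1 to 12.9, adjusted p = 0.0476). Of these 11 genes 9 passed without ICI 1 or ICI 2, 10 without ICI 3, 2 without ICI 4, 3 without RI 1 or RI 5, 4 without RI 2 and 5 without RI 4, with adjusted p of at most 0.120.

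MHC class I presentation had 0 of 13 genes past limma and 2 at an unadjusted p under 0.05. Limma voom called 1, quantile normalization 3 and array weights 2, all of them higher in RI, and 1 rose with a mean FPKM of at least 5, with median centring, without ICI 3, after the length and GC correction and with the total without mitochondrial and unmatched genes. Its median was −0.0336 on the log2 scale, 0.0589 with TPM and 0.33 after quantile normalization.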
